A study of Homo sapiens with 8 samples.

How the data were processed

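Total RNA from H9 human embryonic stem cells was sequenced in 4 WT and 4 EXT1-/- libraries after 28 h of mesendoderm induction with 6 µM CHIR-99021; per the labels' protocols a stranded total RNA kit was used. Groups and replicate numbers were taken from the sample titles. Per the submitters' processing notes the tools were STAR, RSEM and edgeR, with GRCh38.p10 as the genome build and no versions given. A single deposited table held the authors' comparison of the groups and 8 columns of values per library, and 0 columns of other samples.

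The columns per library are a normalised signal, not raw counts: the authors deposited whole numbers whose effective library sizes, computed here with an own implementation of the trimmed mean of M values, lay between 38891466 and 38902443 in all 8 libraries, which raw counts would not show. Low values fell on combs that gave a scale factor between 0.934 and 1.053 in 6 of the 8 libraries and were not resolved in the other 2, so whole reads were not recovered. These values are called normalised read counts. Their totals per library were 37737058 to 40017763, and 1 CPM is 38.9 of them. The table also holds a log2 fold change, a log2 CPM, a likelihood ratio score, a p-value and an FDR per gene that the authors deposited; values from it are named as the authors'. The second-highest value of each gene was at least 0.977 CPM and the third-highest was 0 in some, so low genes had been left out of the table at about 1 CPM in 2 libraries; genes outside it were not analysed here.

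The test written down before the data were examined was a quasi-likelihood test on counts, with limma as the replacement if only normalised values were found. The replacement was used: log2(value + 1), limma 3.58.1 with an intensity trend, genotype as the only term, and Benjamini-Hochberg adjustment over 15811 genes with 0.05 as the threshold. A mean of at least 1 in either group was required, which removed no gene. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. Count models (the quasi-likelihood test of edgeR, and DESeq2) were not run because the values are not counts. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3 were used.

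Before the data were examined, 28 gene lists were fixed: heparan sulfate synthesis, its core proteins, chondroitin and dermatan sulfate synthesis, linkage region and sulfate donor, primitive streak, definitive endoderm, mesoderm, pluripotency, neuroectoderm, neural crest, amnion and trophectoderm, Wnt targets, Wnt ligands and receptors, Nodal/Activin, BMP targets, FGF/ERK targets, FGF ligands and receptors, mesenchymal genes, epithelial genes, matrix, HOX genes, cell cycle, p53 targets, glycolysis and hypoxia, cholesterol synthesis, mitochondrially encoded proteins, endothelial and blood cells, and feeder fibroblasts. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists, with an estimated correlation and fry beside it. Genes were named by a rule also fixed then: EXT1; the 8 higher and 8 lower genes with the largest fold past the threshold, at least 2-fold, at least 1 CPM in the higher group, no overlap between groups, a protein-coding annotation and a symbol that is not a clone, LOC or LINC name; up to 4 members with the smallest adjusted p in each list with a member past the threshold; and always TBXT, MIXL1, EOMES, GSC, SOX17, MESP1, POU5F1, NANOG, SOX2, AXIN2, LEFTY1 and DUSP6. The values of 4 genes that this rule names are not reported here. Protein-coding status was read from GENCODE 29, to which 15777 genes (99.8%) were matched and which gave the coordinates.

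Library sets were found from the data by the largest gap in the mitochondrial share. Within a group, the chi-square per degree of freedom over genes was 72.6 to 119.6 between libraries of different sets and 4.43 to 10.8 within a set, so no pair of libraries agreed within sampling noise. The fit was tested on simulated data made from these libraries, with 200 of 15811 genes changed. Where library sets were simulated, the fit without a set term recovered 20% of 1.25-fold, 66% of 1.5-fold, 94% of 2-fold and 100% of 4-fold changes with 0 false calls, and with a set term it recovered 92% of 1.25-fold changes and 100% of the larger ones, with 3.92% of calls false. Without simulated sets, 6.25% of calls were false, and 6.73% with a set term. The changed genes had a mean of at least 100 normalised counts, so recovery of lower genes was not tested. All genes shared 1 dispersion, and the set effect of a gene was constant, as the set term models it. Ratios of near-silent genes carry 95% exact binomial (Clopper-Pearson) intervals that treat the normalised values as counts. Alternatives were other scalings, filters, pseudocounts and tests, a replicate block, and each library left out; after the data were seen, the library set as a term, each set alone, removal of GC and length trends, the library set together with an estimated correlation or fry, and 3 further gene lists were added.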

Results

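Total RNA sequencing was carried out on H9 cells, an established human embryonic stem cell line, in 2 groups of 4 libraries: wild type (WT), and an EXT1-/- line made with CRISPR/Cas9. EXT1 encodes a glycosyltransferase that, with EXT2, builds the sugar chain of heparan sulfate, and the labels describe the EXT1-/- cells as lacking this glycan. Both groups were taken after 28 h in 6 µM CHIR-99021, a GSK3 inhibitor that switches on β-catenin signalling and drives stem cells towards mesendoderm, the shared precursor of mesoderm and endoderm. The deposited table lists 15811 genes, and the normalised read counts of a library summed to between 37737058 and 40017763. The comparison of the groups asks how induced cells without heparan sulfate differ from induced WT cells. No uninduced library was analysed here, so differences present before induction cannot be separated from differences in the response. Libraries fell into 2 sets that the labels do not name: mitochondrially encoded transcripts took 10.67% of the counts in WT replicate 1, 9.18% in EXT1-/- replicate 1 and 9.38% in EXT1-/- replicate 4, against 5.30 to 5.43% in the other 5 libraries. These are called the high and the low set, and the medians of gene lists within the low set (3 WT and 2 EXT1-/- libraries) are given beside those of all 8. The high set holds 1 WT library. Of 109 named genes besides EXT1, 107 kept their call and direction within the low set, and UXS1 and GSC did not. Apart from those always named, these genes were picked by fold change or adjusted p in all 8 libraries. The low set is part of these, so this agreement is largely built in by the selection. The labels do not say that replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical, and a single EXT1-/- line stands for the genotype.

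EXT1 itself (ENSG00000182197, chromosome 8, 117794490 to 118111853 on the minus strand of GRCh38, GENCODE 29) was read first as a check of the labels. Its normalised count was 1776, 1499, 1464 and 1508 in WT replicates 1 to 4 and 890, 894, 915 and 980 in EXT1-/- replicates 1 to 4. The means were 1562 ± 144 (SD, n = 4) and 919.8 ± 41.6 (SD, n = 4), a log2 fold change of -0.76 ± 0.07 (SE) with an adjusted p of 9.20e-05 by limma. A two-sided exact permutation test over the 70 ways of dividing the 8 libraries gave p = 0.0286, the smallest this design allows. The log2 fold change was -0.72 within the low set and -0.93 within the high set. The transcript was therefore lower in the EXT1-/- libraries but still present, and the table does not show which exon was edited.

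Across the genome, 5063 of the 15811 genes tested (32.0%) differed between the groups at an adjusted p below 0.05 (limma, Benjamini-Hochberg), of which 2405 were higher and 2658 lower in EXT1-/- cells. At least a 2-fold difference was found for 1110 genes, 433 higher and 677 lower. With the library set as a term in the model the counts were 8195 and 1114, and within the low set they were 7111 and 1116. All 5063 genes remained called with the set term, and 100% of them had the same sign within both sets. They were called from libraries of both sets, so this shared sign is largely built in by the selection. Of the 7111 genes called within the low set alone, 6765 had the same sign in the high set. The authors' deposited table marks 4144 genes at an FDR of 0.05, 1996 higher and 2148 lower; 3820 of these were among the 5063, each in the same direction. In 5293 genes (33.5%) the values of the groups did not overlap, where chance alone gives 2.86%.

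Among protein-coding genes with a full gene symbol, the 8 with the largest rise included the transcription factor genes TFAP2A, HAND1, DLX5, MEIS2 and ZIC1. GREB1L, a cofactor of retinoic acid signalling, went from 56.8 ± 8.06 to 3571 ± 456 normalised counts (SD, n = 4 in each group), a log2 fold change of 5.95 ± 0.13 (SE). TFAP2A, a regulator of surface ectoderm and neural crest, went from 3.25 ± 1.71 to 188.8 ± 68.3, and DLX5, a homeobox gene of the neural plate border, from 3.75 ± 2.87 to 116.2 ± 45.0. HAND1, a factor of lateral mesoderm and extraembryonic tissue, had a summed normalised count of 2 in the 4 WT libraries and 249 in the 4 EXT1-/- libraries, a ratio of 124.5 with a 95% counting interval of 34.1 to 1034. MEIS2 rose from 62.5 ± 11.3 to 1432 ± 221, ZIC1 by a log2 fold change of 4.46 ± 0.19, LIX1 by 4.44 ± 0.08 and MOBP by 5.02 ± 0.32. For these 8 genes the adjusted p lay between 2.29e-08 and 6.57e-05 (limma).

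The 8 genes with the largest fall, chosen among protein-coding genes with a full gene symbol, were near silent in EXT1-/- cells. PUS7L (chromosome 12, 43718993 to 43758817, minus strand), a pseudouridine synthase gene, summed to 3873 normalised counts over the WT libraries and 7 over the EXT1-/- libraries, a ratio of 553 with a 95% counting interval of 268 to 1377. Its neighbour IRAK4 (43758944 to 43789543, plus strand), a kinase of Toll-like receptor signalling, summed to 509 and 1. The zinc finger genes ZNF726, ZNF717 and ZNF596 summed to 1199, 347 and 244 in WT cells and to 2, 6 and 0 in EXT1-/- cells, so ZNF596 was at least 81.3-fold lower against a floor of 3 counts over the group. CAT, which encodes catalase, fell from 516 to 4, C9orf64 from 382 to 6 and CYP4F22, a gene of skin ceramide synthesis, from 156 to 3. Adjusted p values ran from 7.44e-07 to 0.000190 (limma). By a threshold set after the values were seen (a sum of at most 10 in one group and a mean of at least 1 CPM in the other), 14 genes were near silent in EXT1-/- cells and 2, HAND1 and ANO3, in WT cells. Zinc finger genes of this family have close copies, so their counts are uncertain, and the intervals cover counting error only.

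Targets of FGF and ERK signalling were mostly lower in EXT1-/- cells. Of 20 measured genes, 18 were lower, 1 was higher and 1 did not pass, with a median log2 fold change of -1.91 (-1.95 within the low set). Adjusted over the list alone, 19 were lower and 1 higher. DUSP6, a phosphatase that is induced by ERK and acts back on it, fell from 653.5 ± 40.6 to 46.0 ± 8.0 normalised counts (SD, n = 4 each; log2 fold change -3.81 ± 0.12, adjusted p 3.34e-07, limma). The log2 fold change was -3.56 for ETV5 and -3.06 for ETV4, which encode ETS factors, and -2.66 for the early response gene IER3. CCND1, cyclin D1, was the member that was higher, at 0.68 ± 0.06. As a list it lay below other genes (camera, adjusted p 1.72e-13), a call lost with an estimated correlation (adjusted p = 0.177). FGF ligands and receptors went both ways, with 6 of 16 higher and 5 lower (7 and 5 adjusted over the list alone) and a median of 0.21 (0.10 within the low set). FGF4 fell from 597.0 ± 87.2 to 166.0 ± 33.3 and FGF13 from 1942 ± 130 to 684.5 ± 57.8, whereas FGFR3 rose from 208.2 ± 27.0 to 726.0 ± 65.3 and FGF18 from 524.0 ± 78.9 to 1686 ± 386; the list was not called (camera, adjusted p 0.413).

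**Figure D1:**
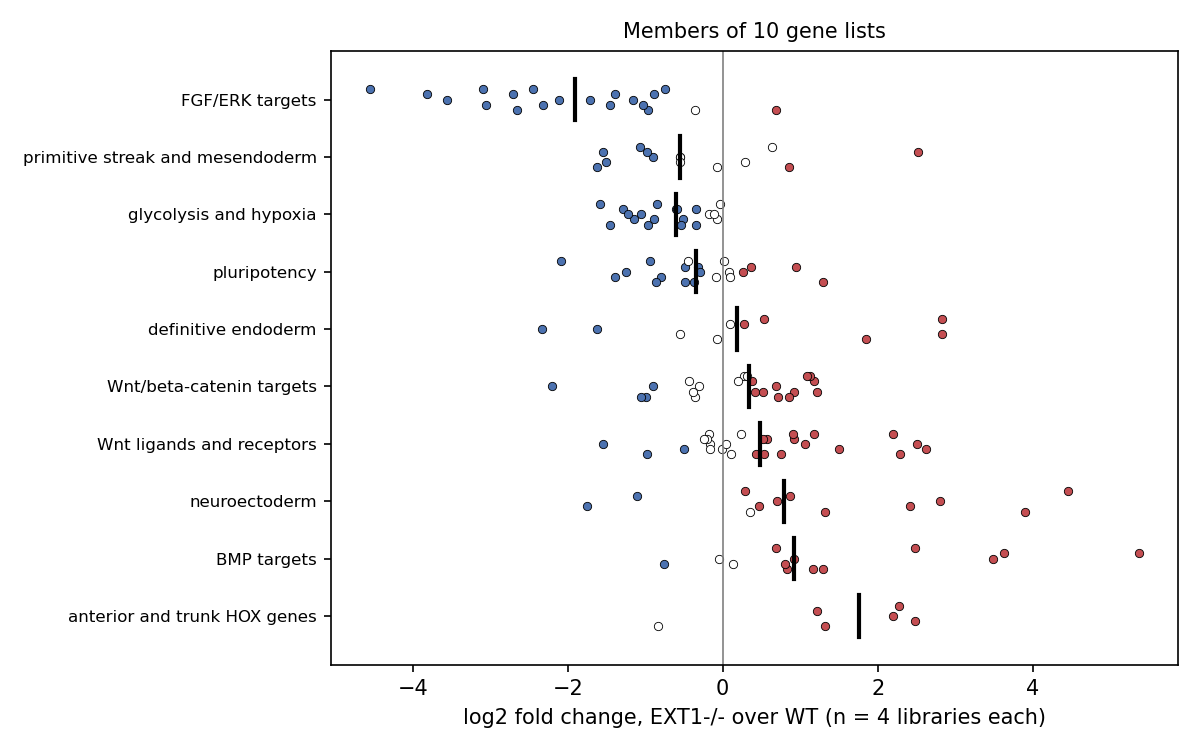
Each point is a member of 1 of 10 gene lists, placed at its log2 fold change of EXT1-/- over WT (4 libraries each). Red and blue points passed an adjusted p of 0.05 (limma), white points did not, and black bars are list medians: -1.91 for FGF/ERK targets at the top and 1.76 for the HOX genes at the bottom.

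Markers of the induced fate were still expressed in EXT1-/- cells, at lower levels for several of them. Among 14 measured primitive streak and mesendoderm genes, 6 were lower, 2 higher and 6 did not pass, with a median of -0.55 (7 lower and 3 higher adjusted over the list alone). Within the low set 9 were lower and 3 higher, with a median of -0.86. EOMES, a T-box factor needed for endoderm, fell from 7304 ± 578 to 2580 ± 420 normalised counts, MIXL1 from 14762 ± 1102 to 5161 ± 1212, and TBXT, the classical primitive streak factor Brachyury, from 6558 ± 510 to 3584 ± 910 (SD, n = 4 each). NODAL fell by 1.07 on the log2 scale, while FGF17 was higher by 2.52. GSC had a log2 fold change of -0.55 and an adjusted p of 0.0817 (limma), which did not pass; it did without EXT1-/- replicate 4 (-0.70, adjusted p 0.0366), within the low set (-0.75, adjusted p 0.0349) and with GC and length trends removed (-0.99, adjusted p 0.00660). The list as a whole missed the threshold (camera, adjusted p 0.0532; 0.687 with an estimated correlation), but passed without WT replicate 2 (0.0452), without EXT1-/- replicate 4 (0.0182), with limma-voom (0.0486) or with GC and length trends removed (0.0381). SOX17 and MESP1 were not analysed here.

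Later derivatives moved in both directions. The mesoderm and definitive endoderm lists held 24 and 18 genes, and members absent from the deposited table were not counted. HAND1, TBX3 and PRDM1, which were higher in EXT1-/- cells, had mean WT counts of 0.5, 26.0 and 21.2. They could not have entered that table on WT values alone, so the counts of these 2 lists lean towards rises. Of 10 mesoderm genes, 3 were higher and 3 lower: KDR, a VEGF receptor, fell from 10328 ± 347 to 1648 ± 141 and APLNR, the apelin receptor, from 1015 ± 81.0 to 97.8 ± 14.6, whereas BMP4 rose from 117.8 ± 9.91 to 416.2 ± 71.5 and TBX3 from 26.0 ± 5.35 to 165.0 ± 50.5 (SD, n = 4 each). The median of that list was -0.11 (-0.16 within the low set), its mean 0.15, and it was not called (camera, adjusted p 0.595), but was called lower among genes of at least 5 CPM in at least 4 libraries (0.0307). Of 10 definitive endoderm genes, 5 were higher and 2 lower (5 and 3 adjusted over the list alone), with a median of 0.18 (0.15 within the low set). The chemokine receptor gene CXCR4 rose by 2.83, PRDM1 by 2.84 and GATA4 by 1.84 on the log2 scale, while HHEX fell by 2.33, and the list was not called (camera, adjusted p 0.178) except with that stricter filter, as higher (0.00582). In the Nodal/Activin list, 3 of 15 genes were higher and 3 lower (adjusted p 0.835; median -0.01), and within the low set 5 were higher and 5 lower (median 0.02). The co-receptor gene TDGF1 fell by 2.09, whereas LEFTY1, a Nodal antagonist, rose by 1.22 ± 0.28.

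Pluripotency genes were mostly lower. Of 20 measured, 11 were lower, 4 higher and 5 did not pass (median -0.35, and -0.33 within the low set; camera, adjusted p 0.0148; adjusted p = 0.328 with an estimated correlation). POU5F1, which encodes OCT4, fell from 59306 ± 2595 to 32616 ± 1291 normalised counts, NANOG from 3646 ± 249 to 1902 ± 120 and DPPA4 from 18044 ± 609 to 7628 ± 465 (SD, n = 4 each). L1TD1 fell by 1.39 on the log2 scale. SOX2, a factor shared by pluripotent and neural cells, went the other way, from 5922 ± 1688 to 11246 ± 2355 (log2 fold change 0.94 ± 0.21, adjusted p 0.00815, limma).

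Among genes in the deposited table, neuroectoderm genes and BMP targets were mostly higher in EXT1-/- cells. Of 12 neuroectoderm genes, 9 were higher, 2 lower and 1 did not pass (median 0.79, and 0.59 within the low set; camera, adjusted p 0.00128; adjusted p = 0.328 with an estimated correlation). Besides ZIC1, the POU factor gene POU3F2 went from 12.5 ± 1.91 to 92.8 ± 11.6 normalised counts and OTX1 from 18.8 ± 5.06 to 299.8 ± 110 (SD, n = 4 each), while OTX2 fell from 113.8 ± 21.2 to 33.0 ± 4.69. In the neural crest list, 4 of 7 genes were higher and 2 lower, with a median of 2.49 (2.17 within the low set). PAX3 rose from 83.0 ± 2.16 to 878.8 ± 153, MSX1 from 453.0 ± 73.6 to 6108 ± 3254 and MSX2 from 111.5 ± 15.8 to 641.5 ± 184; the list missed the threshold (camera, adjusted p 0.0662; 0.443 with an estimated correlation) and passed without EXT1-/- replicate 4 (0.0435) or with upper quartile factors (0.0498). Targets of BMP signalling were higher in 10 of 13 cases and lower in 1 (median 0.91, and 0.72 within the low set; camera, adjusted p 4.47e-05; adjusted p = 0.328 with an estimated correlation). ID2, an inhibitor of differentiation factors, rose from 8471 ± 466 to 15097 ± 935. Of 6 anterior and trunk HOX genes measured, 5 were higher and none lower (1 lower adjusted over the list alone, and within the low set), with a median of 1.76, and 1.53 within the low set (camera, adjusted p 0.00890; adjusted p = 0.328 with an estimated correlation): HOXA2, HOXA3 and HOXB2 rose by 2.48, 2.20 and 2.27 on the log2 scale. These lists held 21 HOX, 22 neuroectoderm, 14 neural crest and 17 BMP target genes, and members absent from the deposited table were not counted. Mean WT counts of HOXA2, HOXA3 and HOXB2 were 14.8, 31 and 9.25, below 1 CPM. They could not have entered the table on WT values alone, so counts in such lists lean towards rises. Among 10 amnion and trophectoderm genes 5 were higher and 2 lower (median 0.59, and 0.49 within the low set). TFAP2A, TBX3 and HAND1 were higher and GABRP was lower by -2.79. That list passed with all 8 libraries (camera, adjusted p 0.0415; adjusted p = 0.328 with an estimated correlation) but not with the library set as a term (0.103), within the low set (0.0979), without EXT1-/- replicate 2 (0.0546), with limma-voom (0.0522) or with the filter of 5 CPM in 4 libraries (0.164).

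**Figure D2:**
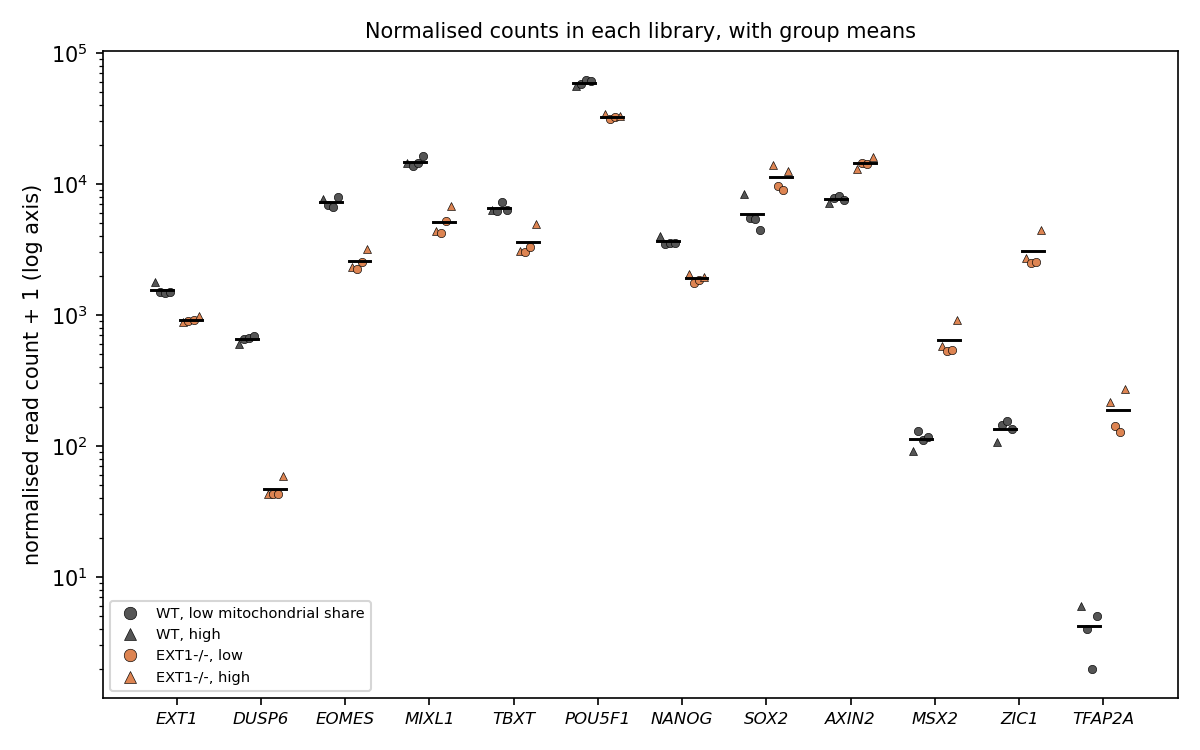
Normalised read count plus 1 on a log axis for 12 genes in each of the 8 libraries. Grey points are WT and orange points EXT1-/- libraries, triangles are the 3 libraries with a high mitochondrial share, and black bars are group means, such as 653.5 and 46.0 before adding 1 for DUSP6. In each gene shown the WT and EXT1-/- libraries of the low set do not overlap.

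Wnt pathway genes did not share the fall of the FGF targets. Both groups were induced with a GSK3 inhibitor that switches on β-catenin signalling. These values therefore do not show how cells without heparan sulfate respond to Wnt ligands. Of 22 β-catenin targets, 11 were higher, 4 lower and 7 did not pass (median 0.35; 11 higher and 6 lower adjusted over the list alone). Within the low set 12 were higher and 8 lower (median 0.27). The list was not called (camera, adjusted p 0.0858; 0.738 with an estimated correlation) except, as higher, with the filter of 5 CPM in 4 libraries (0.0347). AXIN2, a feedback inhibitor of the pathway, rose from 7644 ± 412 to 14532 ± 1266 normalised counts, RNF43 from 2175 ± 257 to 4766 ± 515 and TNFRSF19 from 3326 ± 428 to 7068 ± 769 (SD, n = 4 each). Wnt ligands and receptors were higher in 14 of 26 cases and lower in 3 (median 0.48, and 0.36 within the low set; camera, adjusted p 0.00732; adjusted p = 0.328 with an estimated correlation; 0.120 with the filter of 5 CPM in 4 libraries). FZD1 rose from 515.5 ± 58.0 to 1465 ± 242 (SD, n = 4 each), and WNT5A from 86.2 ± 10.8 to 493.2 ± 61.1. WNT8A was higher by 1.18 on the log2 scale, and the secreted antagonist gene SFRP2 fell by 1.55.

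Lists of heparan sulfate and related glycan genes were not called by camera, and fry called only that of the linkage region and sulfate donor among them (adjusted p 0.00276), a call lost with the library set as a term (0.109). Apart from EXT1, 5 of 19 heparan sulfate synthesis genes were higher and 6 lower (camera, adjusted p 0.944), with a median of 0.09 and a mean of -0.16. Within the low set 3 were higher and 5 lower, with a median of -0.01. HS6ST2 fell from 643.0 ± 103 to 214.8 ± 44.3 normalised counts and the sulfatase gene SULF1 from 140.8 ± 25.1 to 46.8 ± 15.0 (SD, n = 4 each), while GLCE rose by 0.58 and HS3ST3B1 by 0.57 on the log2 scale. Core proteins were higher in 7 of 15 cases and lower in 3 (7 and 5 adjusted over the list alone, and within the low set; camera, adjusted p 0.413), with a median of 0.14 and 0.04 within the low set: NRP1 rose by 2.69 and GPC3 by 0.72, CD44 fell from 1532 ± 153 to 737.8 ± 86.7, and the log2 fold change of GPC6 was -0.85. Chondroitin and dermatan sulfate genes were higher in 4 of 13 cases and lower in 5 (5 and 5 adjusted over the list alone; adjusted p 0.655), and the median was -0.01 (-0.09 within the low set), with DSEL lower by -1.38, DSE by -0.54, CHSY1 by -0.45 and CHST12 higher by 0.86. For the linkage region and sulfate donor, 2 of 12 genes were higher and 2 lower (adjusted p 0.542), and within the low set 1 was higher and 2 lower (median 0.04, and 0.02 within the low set). XYLT1 was higher by 0.55 and PAPSS2 and PAPSS1 lower by -0.40 and -0.27. UXS1 was higher by 0.24 (adjusted p 0.0329, limma), a call that was lost without WT replicate 2 (0.101), WT replicate 3 (0.0750), WT replicate 4 (0.0525), EXT1-/- replicate 1 (0.0802) or EXT1-/- replicate 4 (0.0760). It was lost as well within the low set (0.16, adjusted p 0.0562), with upper quartile factors (0.0521) and in the authors' deposited table (FDR 0.0797).

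Genes of glycolysis and of cholesterol synthesis were lower in EXT1-/- cells. Of 19 glycolysis and hypoxia genes, 15 were lower, none higher and 4 did not pass (median -0.61, and -0.67 within the low set; camera, adjusted p 1.27e-08; adjusted p = 0.328 with an estimated correlation). LDHA, lactate dehydrogenase, fell from 44570 ± 6077 to 14760 ± 1593 normalised counts, the glucose transporter gene SLC2A3 from 29022 ± 1357 to 12394 ± 211, PDK1 from 19679 ± 1129 to 8920 ± 593 and BNIP3 from 12706 ± 1570 to 5204 ± 517 (SD, n = 4 each). Of 20 cholesterol synthesis genes 10 were lower and none higher (12 lower adjusted over the list alone; median -0.23, and -0.31 within the low set; camera, adjusted p 0.00258; adjusted p = 0.328 with an estimated correlation), with FDFT1 lower by -0.37 and SC5D by -0.23. The call of SC5D was lost with GC and length trends removed (-0.13, adjusted p 0.159) and in the authors' deposited table (FDR 0.0553). In the cell cycle list, 7 of 22 genes were higher and none lower (8 higher adjusted over the list alone), by small amounts (median 0.11; camera, adjusted p 0.0113; adjusted p = 0.247 with an estimated correlation), and within the low set 13 were higher (median 0.15). RRM2 rose by 0.46, CCNE1 by 0.45, MCM2 by 0.36 and MCM4 by 0.27, and the call of MCM4 was lost in the authors' deposited table (FDR 0.0655). Of 17 p53 targets, 3 were higher and 8 lower (median -0.35), and within the low set 1 was higher and 10 lower (median -0.26). PMAIP1, which encodes the cell death protein NOXA, fell from 7559 ± 1115 to 2345 ± 323, the log2 fold changes of SPATA18 and BTG2 were -1.16 and -0.78, whereas the cell cycle inhibitor gene CDKN1A rose from 846.5 ± 113 to 2572 ± 443. The p53 list passed with all libraries (camera, adjusted p 0.0440; adjusted p = 0.625 with an estimated correlation) and missed without WT replicate 2 (0.0606), WT replicate 3 (0.0628), WT replicate 4 (0.0511), EXT1-/- replicate 1 (0.0683) or EXT1-/- replicate 4 (0.0676).

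Epithelial and matrix genes went both ways. Of 20 epithelial genes 8 were lower and 4 higher (median -0.16, and -0.16 within the low set): EPCAM fell from 12243 ± 873 to 4958 ± 255 normalised counts, and the log2 fold changes of RAB25, ESRP1 and ST14 were -0.86, -0.70 and -1.02. The list passed with all libraries (camera, adjusted p 0.0440; adjusted p = 0.355 with an estimated correlation) and missed within the low set (0.0583), without WT replicate 1 (0.0801), EXT1-/- replicate 2 (0.0603) or EXT1-/- replicate 3 (0.0667). Of 21 extracellular matrix genes 9 were lower and 4 higher (10 and 5 adjusted over the list alone; median -0.25, and -0.20 within the low set). Fibronectin, FN1, fell from 9906 ± 969 to 4401 ± 176 and SPARC from 7512 ± 253 to 4088 ± 178, FBN2 fell by 0.72, and VCAN rose from 45265 ± 2469 to 67723 ± 2090 (SD, n = 4 each). That list passed (camera, adjusted p 0.0336; adjusted p = 0.443 with an estimated correlation) except without WT replicate 1 (0.0645) or EXT1-/- replicate 3 (0.0541). Mesenchymal genes were higher in 6 of 14 cases and lower in 4 (7 and 4 adjusted over the list alone; adjusted p 0.655), and within the low set 7 were higher and 6 lower (median 0.15, and 0.04 within the low set). VIM rose from 9210 ± 391 to 25494 ± 4792, and TAGLN fell by 0.59.

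Markers of other cell types were few. Among feeder fibroblast genes 5 were measured, of which COL1A1, COL1A2 and THY1 were lower by -0.62, -0.71 and -0.91 and PRRX1 was higher by 3.02; the median was -0.62 (-0.66 within the low set) and the mean 0.15 (camera, adjusted p 0.534). Of 3 endothelial and blood genes measured, TEK rose from 591.0 ± 27.0 to 1550 ± 49.8 (SD, n = 4 each) and the others did not pass (adjusted p 0.0800; median 0.21, and 0.16 within the low set). None of the 13 mitochondrially encoded protein genes passed with all 8 libraries (median 0.23, camera adjusted p 0.375). Within the low set 5 were higher (median 0.03). As a list they were called higher without WT replicate 1 (camera, adjusted p 0.0212). That fit leaves high-set libraries in EXT1-/- only, so its call cannot be told apart from the library sets. With the library set as a term the list was not called (camera, adjusted p 0.991). The sets were defined by the share of mitochondrially encoded transcripts, so fits by set are no independent check of this list. In all, 13 of the 28 lists were called by camera, 6 higher and 7 lower, and with an estimated correlation 0 were called, 3 having an unadjusted p below 0.05; fry, which does not compare a list with other genes, called 21. Those 21 held the 13 and the lists of primitive streak, definitive endoderm, mesoderm, neural crest, β-catenin targets, linkage region and sulfate donor, endothelial and blood cells, and feeder fibroblasts. With the library set as a term fry called 18, without the linkage region (adjusted p 0.109), primitive streak (0.0530) and feeder fibroblasts (0.804). Except where stated, counts adjusted over the list alone were those given, which held for 16 of the 28 lists.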

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

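All tests in this part were run with rules fixed before the values were seen, except the library sets, which were found from the data. Each of 110 named genes, 2 library shares and the library total was taken in each genotype as a group of 4 libraries. Of the 224 such groups whose values were not all equal, 29 held a library far from the other 3, measured as its gap to the nearest library over the range of the group, where chance gives about 1 in 20, or 11.2. In WT cells the library apart was replicate 1 for the mitochondrial share (0.976), the share of the 10 most abundant genes (0.945), GPC3 (0.923), COL1A2 (0.908), NANOG (0.903), THY1 (0.882), ZNF596 (0.870), TNFRSF19 (0.862), EXT1 (0.859), SPATA18 (0.851), HS6ST2 (0.849), DLX5 (0.833) and HOXA2 (0.833). WT replicate 1 is the WT library of the high mitochondrial set. WT replicate 3 stood apart for C9orf64 (0.875), TBXT (0.875) and HOXA3 (0.833), and WT replicate 4 for ST14 (0.893) and ZNF717 (0.864). In EXT1-/- cells the library apart was replicate 4 for DUSP6 (1.000), HOXA3 (0.954), BMP4 (0.887), MSX2 (0.881), ZIC1 (0.880), GATA4 (0.861), POU3F2 (0.840) and TBXT (0.831), replicate 3 for IRAK4 (1.000) and ZNF717 (1.000), both at values of 0 to 2, and replicate 1 for MCM4 (0.868).

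The 35 ways of dividing the 8 libraries into 2 groups of 4 were each fitted. Only 1 split, the genotypes, called as many genes as the 5063 found, and the highest of the others called 1 gene; the same held for the 1110 genes changed at least 2-fold (1 split, highest other 1). For lists called by camera, 1 split reached the 13 called, but the highest other reached 9, and with an estimated correlation 0 lists were called (3 at an unadjusted p below 0.05; fry called 21). Only the genotype split reached the counts of genes and lists, and 1 of 35 is the smallest share this design can give. Each other split mixes the genotypes, which widens the spread within groups and holds down its calls of genes. The splits therefore do not exclude chance, and the count of lists rests on the preset correlation. A difference between cell lines cannot be excluded.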

How the results depend on the processing

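The library set as a term, each set alone, the removal of GC and length trends and the set term with an estimated correlation or fry were alternatives chosen after seeing the data; the others were planned. EXT1 stayed lower and past the threshold in all alternatives (log2 fold change -0.791 to -0.697 with 1 library left out) except with only the 3 libraries of the high set, where it was -0.927 with an adjusted p of 0.0674; that fit has 1 WT library, assumed to vary like the others. Of the other 109 named genes, 103 kept their call and direction in every alternative that tested them besides that fit. Only 87 were tested with the filter of 5 CPM and 103 in the authors' table at a log2 CPM above 0. UXS1, GSC, SC5D, MCM4, HS3ST3B1 and PAPSS1 changed side of the threshold in some, and no named gene or list reversed. Apart from those always named, the genes were picked by fold change or adjusted p in these same libraries, so this stability is largely built in. With only the 3 libraries of the high set, 122 genes were called (71 higher, 51 lower), 108 of them at least 2-fold (63 higher, 45 lower), with fewer libraries tested. The library set as a term raised the count of genes to 8195 (4142 higher, 4053 lower), which included all 5063. In simulated libraries with such sets the term also raised the share of small changes recovered, but their set effect was built as the term models it. The authors' deposited table at an FDR of 0.01 called 2903 genes (1327 higher, 1576 lower), by a stricter threshold. The filter of 5 CPM in 4 libraries left 11721 genes and 516 changed at least 2-fold (212 higher, 304 lower), with fewer genes tested. With 1 library left out, 3721 to 6041 genes were called, 1059 to 1174 at least 2-fold, and 11 to 14 lists. An estimated correlation called 0 lists, with or without the library set as a term (0), and fry, which does not compare a list with other genes, called 21; the cause was not tested. The filter on low values removed no gene, so leaving it out tested nothing. The quasi-likelihood test and DESeq2 were not run, because the values are not counts; the authors' deposited table stands in for the likelihood ratio test.

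The correlation of deviations between libraries of the same replicate number, across genes, was 0.783, 0.438, 0.260 and -0.654. Its sign follows the library sets, since only the libraries numbered 4 lie in different sets. Within the low set, WT replicates 2 and 3 correlated less with their own number (0.438 and 0.260) than with the other EXT1-/- library (0.496 and 0.415). WT replicate 1 correlated more with its own number (0.783) than with EXT1-/- replicate 4 (0.672). Whether replicate numbers pair the libraries is therefore not decided. A fit with a replicate block called 4934 genes, 1106 of them at least 2-fold, and 14 lists, adding primitive streak and mesendoderm (adjusted p 0.0368) to the 13, and EXT1 had a log2 fold change of -0.760. What depth limits was not tested, since no simulation varied it; of the smallest changes simulated, 90% were recovered in libraries without sets and 20% in libraries with sets, so the spread between sets limits small changes.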

Other observations

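The tests of the neighbours of near-silent genes and of CpG content were written down before their results were seen; all other tests in this part, and its 3 gene lists, were chosen after. A list of 22 genes of the neural plate border and placodes had 16 members measured. Of these, 14 were higher in EXT1-/- cells and none lower (median log2 fold change 2.86). Members absent from the deposited table were not counted. TFAP2A, DLX5 and HES4, with WT means of 3.25, 3.75 and 7.5, could not have entered it on WT values alone. IRX1 went from a mean normalised count of 34 to 625, ZIC4 from 25.2 to 247.2 and HES4 from 7.5 to 83.0. The list was picked after such genes were seen to rise, so its camera test (adjusted p 2.90e-11; adjusted p = 0.0744 with an estimated correlation) is not independent evidence. Of 17 BMP and GDF ligands and antagonists listed, 12 were measured, of which 6 were higher and 2 lower. BMP5 rose by 1.80, BMP6 by 1.97 and BMP7 by 0.63 on the log2 scale. BMP5, BMP6 and GREM1, which was also higher, had WT means of 18, 14.8 and 4. They could not have entered the deposited table on WT values alone, so this count leans towards rises as well. Among 14 genes of retinoic acid metabolism and response, 6 were higher and 4 lower, with MEIS1 up by 1.83 and ALDH1A1 at -1.53.

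Near silence of 14 genes in EXT1-/- cells was the first pattern weighed. Of 16 genes picked as near silent from the low set alone, 13 of them among the 14, 12 had both EXT1-/- libraries of the high set below its WT library, where chance gives 33.3%, which argues against the library sets for those 12; AC011330.1, ANKRD20A1, AP005263.1 and AC009133.2 did not. Deletions stay open: the 23 nearest expressed neighbours had a median log2 fold change of -0.05 (ZNF100 -1.19, ROBO2 -1.99), but near-silent genes could not count as neighbours, 4 of the 14 (PUS7L and IRAK4, ZNF726 and AC011503.2) adjoin or overlap another, and a median over separate loci would miss a deletion at a few. Silencing at CpG-rich promoters could not be decided: the median observed/expected CpG of the first 500 bases of their transcripts was 0.47, below the bound of 0.6 set beforehand, but genes matched on expression had 0.486 (percentile 44.4), so, as judged after that value was seen, the measure does not pick out such promoters. Loss of EXT1 and a difference that arose in the single EXT1-/- line cannot be told apart here.

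For the fall of FGF/ERK targets, the library sets are argued against by a median of -1.95 within the low set. Without the immediate-early genes EGR1, FOS, FOSL1, IER3 and PHLDA1, the 15 members left had a median of -1.39. The fall therefore does not rest on those 5 genes alone. Handling at harvest stays open, since the 15 are ERK targets as well. A slower exit from pluripotency stays open: the pluripotency list had a median of -0.35, but 11 members were lower and 4 higher, among them KLF4 (1.30) and SOX2 (0.94), and its call is lost with an estimated correlation (adjusted p = 0.328). The list lay -1.90 below the lowest of the Wnt, BMP and Nodal target medians, which is consistent with the hypothesis that FGF signalling, which uses heparan sulfate as a co-receptor, is weaker in EXT1-/- cells. This was found and tested on the same data, and the list call is lost with an estimated correlation (camera, adjusted p = 0.177). Lower FGF4 (log2 fold change -1.85) is another possible source. FGF ligands and receptors went both ways, however, with 6 of 16 higher, among them FGF17 (2.52) and FGF18 (1.67), and 5 lower.

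The third pattern is the rise of neural plate border genes and BMP targets, 27 genes of which 22 were higher and 1 lower. Their median within the low set was 0.89, but the border genes among them were picked for their rise in these libraries. The BMP targets alone had a median of 0.72 within the low set and 1.28 within the high set. For those targets this argues against the library sets. A scaling factor moves all genes alike. The median of the 27 genes lay 1.15 above that of all genes, but this partly restates how the border genes were picked. Scaling is argued against only for the BMP targets, a list fixed beforehand, with a median of 0.91 against 0.01 for all genes. Since the border list was picked for its rise, random lists were set against the 13 BMP targets alone. Their median of 0.91 lay above the highest of 10000 lists matched on expression (0.55). The BMP list held 17 genes, and members absent from the deposited table were not counted. HAND1 and GREM1, with WT means of 0.5 and 4, could not have entered it on WT values alone. Matching on the mean of all libraries does not correct for this, so the BMP median leans towards a rise. The BMP list joined this pattern after its rise was seen, and it shares MSX1 and MSX2 with the border list. Random lists treat members as independent, whereas the estimated correlation of the BMP list was 0.477. With that correlation its call was lost (camera, adjusted p = 0.328). Whether all cells rose or a subset of another fate did cannot be told apart, since bulk values (median 1.17) do not divide among cells, and the hypothesis of a subset may be tested by staining for TFAP2A and TBXT in the same cells.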
